A study of Mus musculus with 4 samples.

How the data were processed

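Genomic DNA from the left ventricle of C57BL/6 mice was profiled by HMST-seq, which reads short sequence tags next to CCGG sites after digestion with a pair of enzymes that cut the same motif. Per the labels' protocols, 3 libraries were made from each sample. HpaII, which does not cut modified sites, gave the "C" library. MspI, which cuts whether the inner cytosine is methylated or not, gave the "C+mC+hmC" library. MspI after glucosylation, which protects 5-hydroxymethylcytosine (5hmC) from the enzyme, gave the "C+mC" library. The 4 samples were wild-type non-infarcted, wild-type infarcted, Neil3-null non-infarcted and Neil3-null infarcted tissue, all 3 days after myocardial infarction, with 1 sample per group.

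The deposited values are a normalized signal per CCGG site and library, made by the authors; the normalization method is not given in the sources used here. Positions are on mm10, per the submitters' processing notes. The aligner, the filters and any pooling of animals are not given in the sources used here. No deposited value was 0, and the number of tags behind a value is unknown because no whole tags could be recovered from the values, so no counting interval is given. The low end of the HpaII signal differed between samples. Its lowest value and 5th percentile were 2.19 and 3.19 in wild-type non-infarcted and 3.16 and 3.58 in wild-type infarcted tissue. They were 1.01 and 4.72 in Neil3-null non-infarcted and 1.03 and 4.41 in Neil3-null infarcted tissue. Whether a floor under low values moved the unmodified index was not tested. The signal of each library summed to between 34161766 and 43985354. Within a sample, the 3 libraries had been brought to nearly the same total signal. This removes the difference in total yield between HpaII and MspI, which carries the absolute level of 5-methylcytosine (5mC) and 5hmC.

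Indices were computed from sums of signal over the sites of a region. The unmodified index is the HpaII signal as a percent of the MspI signal. The 5mC index is the C+mC signal minus the HpaII signal, and the 5hmC index is the MspI signal minus the C+mC signal, both as a percent of the MspI signal. Because of the scaling, an index above 100% or below 0% occurs wherever a region takes a larger share of one library than of another, and the indices are relative values, not shares of DNA molecules. A difference between samples is given in percentage points of the index. Sites had to be listed in all 4 samples and to have a mean signal of at least 10 over the C+mC and C+mC+hmC libraries of the 4 samples, on the 19 autosomes; 912550 of 1110575 listed sites were used.

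Genes were the 20665 protein-coding autosomal genes of a RefSeq table on the same mouse assembly, which gives the start and end of each gene but neither strand nor exons. Promoters could therefore not be placed. In their stead, the end of the gene with more CCGG sites within 1 kb on either side was used, with at least 5 sites, which left 4115 genes. Of these, 223 had at least 5 sites at both ends. Gene bodies ran from 1 kb inside one end to 1 kb inside the other, with at least 10 sites, which left 9739 genes. The levels planned for exons, untranslated regions and CpG islands were not computed, since no genome sequence or exon annotation was used here. Classes of sites by the number of CCGG sites within 500 bp were given in their place.

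With 1 sample per group, no difference between 2 samples has a replicate check, and no p-value is given for one. Genes were counted by a rule of size, a difference of at least 20 percentage points. The median difference of each of 15 gene lists was placed as a percentile among 10000 random lists of genes matched on mean index and number of sites. A list needed at least 5 measured members. Of the 503 genes in the lists, 483 matched an autosomal gene of the table. The error printed beside a gene is a jackknife standard error over its CCGG sites, which measures the spread between sites of the gene and not between animals. The infarct and genotype main effects were fitted with limma 3.58.1 in R 4.3.3 by an additive model over the 4 samples, with 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. Other steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

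The groups, comparisons, lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. Named genes were Neil3 and, per comparison, the 5 with the largest rise and the 5 with the largest fall in 5mC at gene ends and in gene-body 5hmC, leaving out predicted names, and from each list described the 2 largest rises and the 2 largest falls. The gene-body unmodified index, and the naming of genes by it under the same rule, were added after seeing the data, because it does not use the C+mC libraries, one of which stood apart. Counts relative to the median gene, counts without the C+mC libraries, counts without 3 blocks of missing sites, a gene-end window of 2 kb and a simulated count were likewise chosen after seeing the data. In that simulation 2 samples were drawn around the mean signal per site of the 4, with the spread between the Neil3-null samples at sites of like signal, in 20 draws. The count between them was set beside all 4 comparisons. This spread includes any infarct or animal difference. The Neil3-null C+mC libraries correlated at 0.906, but that of wild-type non-infarcted tissue at 0.837 with wild-type infarcted and 0.848 with Neil3-null non-infarcted tissue. For the last 2 comparisons named, the spread may be too low. The planned promoter window from 2 kb upstream to 500 bp downstream was not run, for want of strand.

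The steps were tested on simulated data. For the wild-type infarct comparison over 9739 gene bodies, 200 genes were changed by 40 percentage points in the unmodified index. The size rule recovered 197 of them and also passed 229 of the 9539 unchanged genes. A list of 20 changed genes lay at percentile 100, and 2 of 100 unchanged lists lay outside the central 95% of random lists. For the infarct effect in the additive model over 9739 genes, limma called 161 of the 200 changed genes, 6 unchanged genes, and 0 genes for genotype. The simulated change was alike in both genotypes and larger than any list median of the unmodified index reported below. Its noise was drawn apart for each site, with none shared by a library or an animal. The simulation therefore does not show how well changes of the size seen in the lists are found.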

Results

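DNA modification was measured at CCGG sites in the left ventricle of wild-type mice and of mice lacking Neil3, a DNA glycosylase that removes oxidized bases, in infarcted and in non-infarcted tissue 3 days after myocardial infarction. There were 4 samples, 1 per group, each with 3 libraries. The mice were 8 weeks old. The files listed 1079784 sites in wild-type non-infarcted, 1063635 in wild-type infarcted, 1060295 in Neil3-null non-infarcted and 1063994 in Neil3-null infarcted tissue, and 996020 sites were listed in all 4. The total signal per library was lowest in wild-type infarcted tissue (34161766 in its C+mC library) and highest in wild-type non-infarcted tissue (43985354 in its C+mC+hmC library). The number of tags is unknown. Between samples, log2 signal correlated at 0.942 to 0.959 for MspI, 0.856 to 0.885 for HpaII and 0.837 to 0.906 for the C+mC libraries across sites, which are not independent replicates. The C+mC library of wild-type non-infarcted tissue stood apart from the others. Its correlation with the MspI library of its own sample was 0.551, against 0.709 to 0.735 in the other samples, and with the HpaII library it was 0.505, against 0.372 to 0.450.

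The first question was what the targeted locus looks like in each sample. Neil3 lies on chromosome 8 from 53586867 to 53639065 (mm10). Its span held 20 CCGG sites listed in any sample, of which 19 were listed in wild-type non-infarcted, 17 in wild-type infarcted, 17 in Neil3-null non-infarcted and 15 in Neil3-null infarcted tissue. The site at 53608722 was listed in both wild-type samples, with MspI signals of 18.9 and 19.2, and in neither Neil3-null sample. A further wild-type site, at 53609622, was listed in non-infarcted tissue alone. At the site at 53605558 the HpaII signal was 10.8 and 17.3 in wild-type and 86.4 and 97.3 in Neil3-null tissue, non-infarcted first, with MspI signals of 94.4, 74.8, 109 and 98.0. With neither exons nor the extent of the targeted change at hand, sites outside the replaced part check nothing about the genotype labels.

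Around Neil3, wild-type sites were missing from both Neil3-null samples more often than elsewhere. On chromosome 8, 1103 of 5080 sites listed in both wild-type samples (21.7%) were missing from both null samples between 29 and 44 Mb, and 176 of 1789 (9.84%) between 51 and 59 Mb, the block that holds Neil3. On chromosome 1, 588 of 3677 sites (16.0%) were missing between 168 and 177 Mb. The share on the other autosomes was 0.569%. In the opposite direction, the share of sites of both null samples missing from both wild-type samples was 0.156%, 0.817% and 0.165% in these blocks and 0.309% elsewhere. Sites still listed in the blocks had median ratios of null to wild-type MspI signal of 1.05, 1.07 and 1.07, against 1.08 over all autosomes, blocks included.

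**Figure D1:**
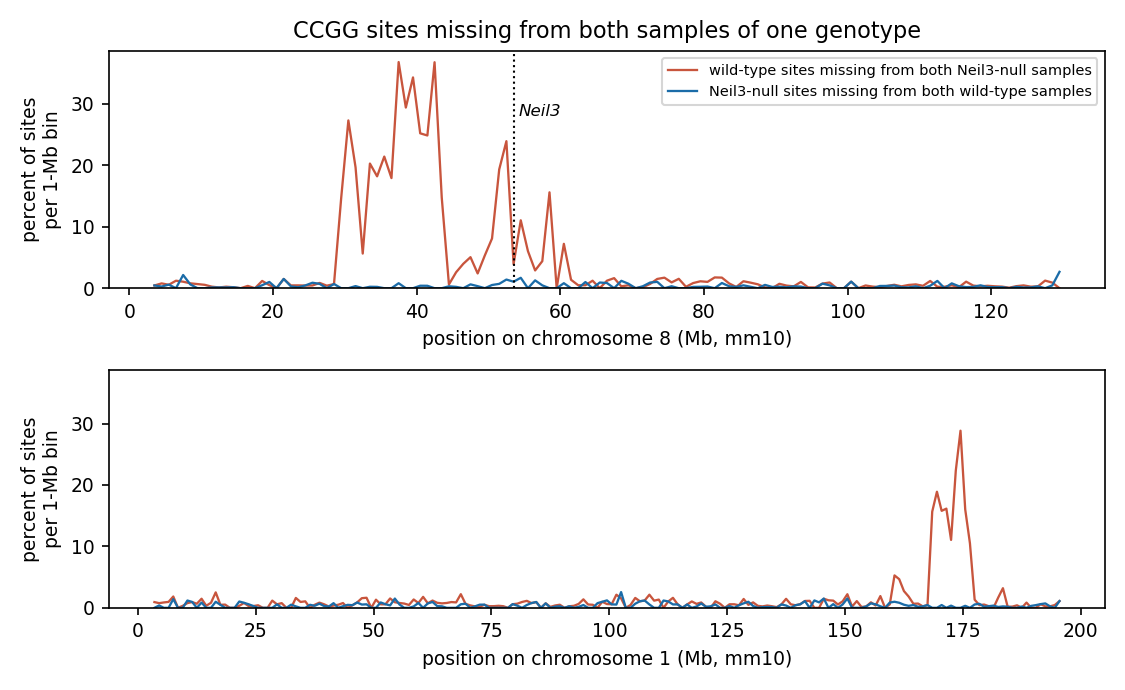
Percent of CCGG sites per 1-Mb bin that were listed in both samples of one genotype and in neither of the other, along chromosomes 8 and 1 (x axis, Mb on mm10). The red line (wild-type sites missing from Neil3-null) is highest in blocks with 21.7%, 9.84% and 16.0% of sites missing, and the dotted line marks Neil3.

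Levels over the whole genome were compared next. The unmodified index separated gene groups of known state: ends of housekeeping genes had a median of 201% to 217% over the 4 samples and ends of germline genes, which are silenced in somatic tissue, 64.2% to 76.6%. Within 1 kb of a gene end the unmodified index was 170% to 176%, and in gene bodies 91.1% to 95.9%. Over all autosomal sites the 5mC index was -2.04% in wild-type non-infarcted, -6.40% in wild-type infarcted, -4.93% in Neil3-null non-infarcted and -6.30% in Neil3-null infarcted tissue. The 5hmC index was 2.94%, 3.53%, 2.49% and 2.43% in the same order. These values lie near 0 because the libraries had been scaled to like totals, so they give no absolute level. The 5mC index differed between infarcted and non-infarcted tissue by -4.36 percentage points in wild-type (-6.89 to -2.17 over 19 autosomes) and -1.37 in Neil3-null (-1.98 to -0.499), and both directions turned under another scaling (14.3 and 3.61 once the libraries were rescaled on unmethylated gene ends). The 5hmC index differed by 0.584 and -0.0530 percentage points, with autosomes on both sides of 0 (-15.1 and -3.86 after that rescaling). Between genotypes, Neil3-null minus wild-type, the 5mC index differed by -2.89 in non-infarcted (7.18 after that rescaling) and 0.101 in infarcted tissue (-3.51 after it, autosomes on both sides of 0 before), and the 5hmC index by -0.458 and -1.10 (-9.16 and 2.03 after that rescaling).

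In wild-type hearts, the infarct comparison asks how modification differs between infarcted and non-infarcted ventricle. Gene bodies of cardiomyocyte markers had a lower unmodified index in infarcted tissue. The list's median difference was -10.1 percentage points, or -13.1 relative to the median of all 9739 genes, below all 10000 matched random lists, and 5 of the 23 measured members lay above the median gene. Gja1, the main gap junction gene of the ventricle, went from 283% to 196% (difference -87.0 ± 21.4 over 10 sites; chromosome 10, 56377300 to 56390419). Xirp1, a protein of the intercalated disc, went from 122% to 88.9% (-33.5 ± 15.2 over 12 sites). Leukocyte markers had a higher index, by 5.31 relative to the median gene (percentile 98.6, 16 of 22 members above the median gene). Mpo, the peroxidase of neutrophil granules, went from 65.4% to 92.9% (27.5 ± 7.85), and Ncf1, a subunit of the phagocyte oxidase, from 170% to 196% (26.1 ± 12.9). Not every member went with its list: the cardiomyocyte genes Tbx20 and Ckm were higher by 22.8 ± 13.8 and 22.1 ± 12.5, and the leukocyte genes Adgre1 and Csf3r differed by -8.64 ± 6.33 and -8.39 ± 10.2.

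Other groups of gene bodies also stood apart in wild-type infarcted tissue. Endothelial markers had a median of -7.33 relative to the median gene (percentile 0.01, 2 of 20 members above it), with the arterial signalling ligand genes Dll4 at -31.4 ± 18.9 and Efnb2 at -20.5 ± 8.63, and the transcription factor genes Tal1 at 43.3 ± 59.2 and Erg at 10.7 ± 3.14. Oxidative metabolism had a median of -5.51 (percentile 0.95), led by the fatty acid oxidation gene Acadm at -29.2 ± 7.69 and the ATP synthase gene Atp5a1 at -23.8 ± 7.96, with Ucp3 at 13.7 ± 18.8 and Sdhb at 13.4 ± 8.45. Base excision repair had a median of -6.48 (percentile 1.26, 2 of 15 members above the median gene), led by the DNA glycosylase genes Smug1 at -33.7 ± 20.6 and Mutyh at -13.9 ± 11.2, with the ligase genes Lig3 at 11.2 ± 8.13 and Lig1 at 4.73 ± 10.9. Inflammation and cytokines had a median of 7.56 (percentile 97.6), led by Lif at 40.7 ± 11.0 and Tnfrsf1b at 25.5 ± 9.23, with Tnfrsf1a at -21.4 ± 17.8 and Cxcl12 at -20.0 ± 15.9. The other lists lay inside the central 95% of random lists: proliferation 4.002, hypoxia and angiogenesis 3.95, DNA methylation and demethylation enzymes -0.398, extracellular matrix and remodelling -1.12, fibroblast and myofibroblast markers -1.18, imprinted genes -1.29, smooth muscle and pericyte markers -1.88, germline genes -2.30 and housekeeping genes -5.15. Of the 15 lists, 6 lay outside, against 0.75 for random draws of genes, which is no test between animals. With sites of mean signal of at least 20 only, the leukocyte list lay at 3.30 (percentile 90.3), base excision repair at -4.75 (percentile 4.10) and oxidative metabolism at -4.21 (percentile 2.64).

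**Figure D2:**
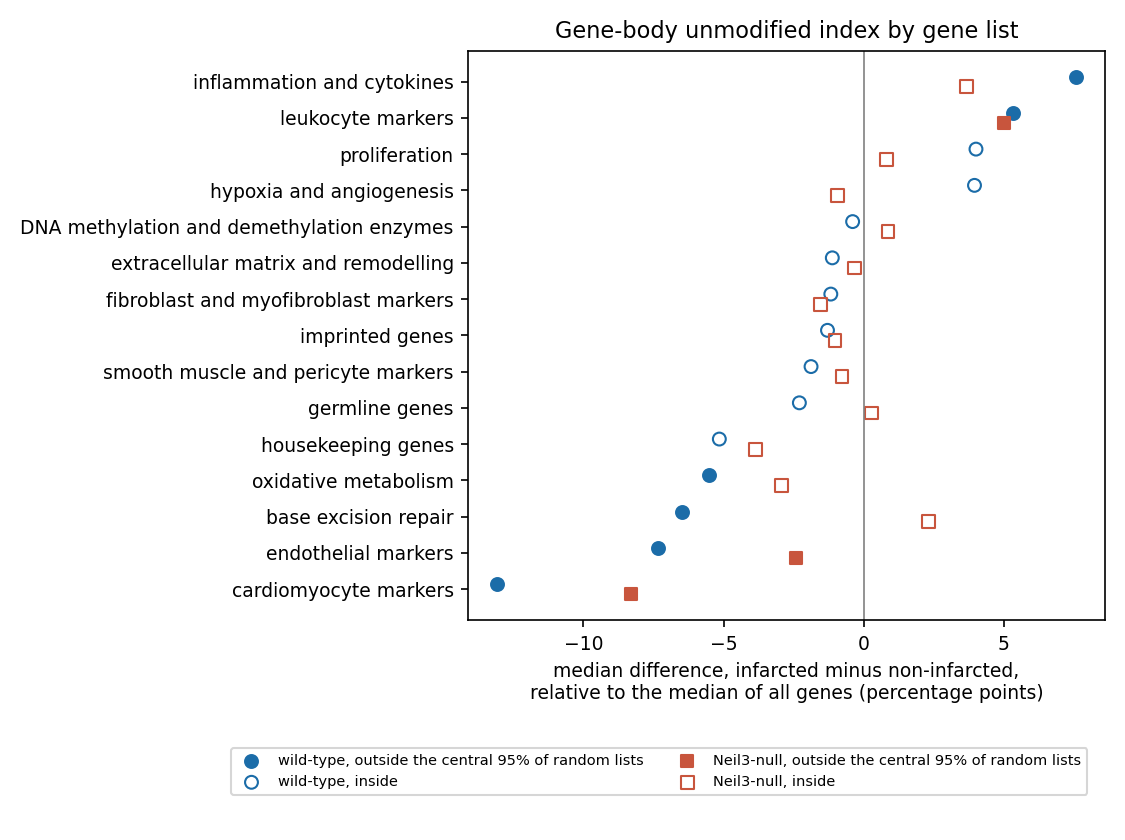
Median difference in the gene-body unmodified index between infarcted and non-infarcted tissue for each gene list, relative to the median of all genes (x axis, percentage points), in wild-type (blue circles) and Neil3-null (red squares). Filled marks lie outside the central 95% of 10000 matched random lists; cardiomyocyte markers lie lowest, at -13.1 and -8.29, and leukocyte markers at 5.31 and 5.00.

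By the size rule, the gene-body unmodified index was higher in wild-type infarcted tissue at 437 genes and lower at 123 of 9739, or 297 and 202 relative to the median gene. With the libraries rescaled to equal totals, 227 were higher and 248 lower, so the balance of directions depends on the scaling. A simulation with equal site means and the spread between the 2 Neil3-null samples, which holds any infarct and animal difference, gave a median of 227 genes. The most positive differences were at Dhh (86.0 ± 29.1), Il17ra (72.1 ± 19.5), Bco2, Cdkn2a and Spring1, and the most negative differences at Gja1, Gtpbp3 (-58.0 ± 25.04), Trim41, the small heat shock gene Cryab (-47.7 ± 16.8) and Blcap.

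At gene ends, the myoglobin gene Mb had the most positive difference in the 5mC index in wild-type infarcted tissue, from -31.3% to 54.1% (85.4 ± 20.2 over 6 sites; chromosome 15, 77015487 to 77050668), followed by Stmn4, Hba-x, Ccn2 and Tff1. The most negative differences were at Dmtn and Fgf17, which share the same 6 sites (-315 ± 158), and at Tnpo2, Pdpn and Zfp536. The index was higher at 256 and lower at 2247 of 4115 genes. The median gene differed by -23.5 percentage points, and relative to it 1070 genes were higher and 1122 lower, against 1383 in the simulation. After rescaling on unmethylated gene ends, 819 were higher and 196 lower. Without the C+mC libraries, which leaves 5mC and 5hmC together, 718 were higher and 1010 lower. None of the 12 lists measured lay outside the central 95% of random lists; the list nearest the edge was housekeeping genes, at 15.6 relative to the median gene (percentile 96.9), followed by cardiomyocyte markers at 22.7 (percentile 94.4) and smooth muscle and pericyte markers at -43.7 (percentile 6.23). In gene bodies the 5hmC index was higher at 592 and lower at 230 genes. The most positive differences were at Dact3 (104 ± 41.0), Six3 (100 ± 23.1), Adcyap1, Hoxc4 and Tnnt1, and the most negative differences at Cep162 (-51.3 ± 12.7), Zbtb5, Spaca3, Eci1 and Klhdc4 (-37.1 ± 6.73). Endothelial markers had a 5hmC median of 6.47 relative to the median gene (percentile 97.6), with Dll4 at 50.9 ± 13.3, Tal1 at 41.4 ± 21.1, Ephb4 at -11.7 ± 8.14 and Erg at -5.06 ± 3.26. The list's percentile was 97.3 at a minimum signal of 5 and 92.9 at 20. Of 15 lists it was the only 1 outside the central 95% in 5hmC, against 0.75 for random draws of genes. Relative to the median gene 689 gene bodies were higher and 159 lower in 5hmC, 848 in all against 231 in the simulation, and after rescaling 3 were higher and 1640 lower. All of these 5mC and 5hmC values use the C+mC library that stood apart.

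The same comparison was made in Neil3-null hearts. Cardiomyocyte markers again had a lower gene-body unmodified index, by -8.29 relative to the median gene, below all 10000 random lists, with 4 of 23 members above the median gene. Xirp1 went from 125% to 99.5% (-25.8 ± 7.27) and Gja1 from 273% to 252% (-21.0 ± 19.3), while Gata4 was at 12.3 ± 6.09 and Myl2 at 2.79 ± 10.9. Leukocyte markers were higher by 5.00 (percentile 99.2, 14 of 22 members above the median gene), led by the myeloid transcription factor gene Irf8 (26.8 ± 7.33) and Mpo (24.1 ± 6.68), with Mrc1 at -8.61 ± 4.92 and Vav1 at -6.77 ± 5.62. Endothelial markers had a median of -2.43 (percentile 2.06), with Efnb2 at -28.8 ± 8.45, Dll4 at -25.0 ± 23.3, Tal1 at 29.8 ± 21.7 and Egfl7 at 16.8 ± 6.82; at a minimum signal of 20 its percentile was 13.1. Base excision repair lay at 2.30 (percentile 89.4), with Smug1 at -24.2 ± 16.0, Polg at -9.17 ± 6.30, Mutyh at 15.8 ± 9.47 and Tdg at 8.10 ± 10.5. Inflammation and cytokines lay at 3.66 (percentile 84.3), and oxidative metabolism at -2.93 (percentile 4.84). The other lists lay at -3.87 (housekeeping genes), -1.56 (fibroblast and myofibroblast markers), -1.03 (imprinted genes), -0.938 (hypoxia and angiogenesis), -0.780 (smooth muscle and pericyte markers), -0.323 (extracellular matrix and remodelling), 0.276 (germline genes), 0.807 (proliferation) and 0.863 (DNA methylation and demethylation enzymes). Of the 15 lists, 3 lay outside the central 95%, against 0.75 for random draws of genes.

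The gene-body unmodified index was higher at 193 and lower at 92 genes in Neil3-null infarcted tissue, or 162 and 110 relative to the median gene (128 and 107 at equal totals), against 227 in the simulation, whose spread came from these same samples. Pax9 (60.9 ± 27.1), Zfp119b, Asb13, Polm and Tph1 had the most positive differences and Dnajb4 (-42.3 ± 27.0), Alox12b, Twf2, Ammecr1l and Cyp2c38 the most negative differences. At gene ends the 5mC index was higher at 462 and lower at 1029 of 4115 genes, with a median gene at -5.06. Relative to it 661 were higher and 774 lower, against 1383 in the simulation, after rescaling 155 were higher and 130 lower, and without the C+mC libraries 682 and 721. The most positive differences were at Bmpr2 (126 ± 77.6), Nadk2, Hrct1, Cdc73 and Eif2ak3 (79.4 ± 79.8) and the most negative differences at Brpf3 (-180 ± 148), Cdk2 (-160 ± 171), Rgl3, Cdca7 and Lrp6. The oxidative metabolism list lay at 22.4 relative to the median gene (percentile 99.8), led by Cycs at 50.9 ± 21.9 and Hadha at 28.6 ± 14.9, with Ppargc1a at -43.3 ± 37.8 and Acadm at -29.4 ± 42.1. It lay at 0 (percentile 54.2) when levels were clipped per site. The gene-body 5hmC index was higher at 83 and lower at 87 genes (97 and 93 at equal totals; 118 and 60 relative to the median gene, 178 in all against 231 in the simulation), and higher at 0 and lower at 24 after rescaling on unmethylated gene ends. Ap5b1 (38.8 ± 17.0), Macc1, Riiad1, Sh2d6 and Pou3f3 had the most positive differences, and Tob2 (-35.2 ± 15.5), Anxa9, Pvalb, Sox10 and Prss36 the most negative differences. None of the 15 lists stood apart in 5hmC.

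The infarct difference was then compared between the genotypes, which share no library in these differences. In the gene-body unmodified index, 46 genes were at least 20 percentage points higher and 27 lower in both genotypes relative to the median gene, against 4.94 and 2.28 if independent, and 12 went opposite ways. Independence is a low baseline, since genes that vary widely could pass in both genotypes in any direction. No expected number was computed for the opposite ways. The genes lower in both included the cardiac troponin gene Tnnt2 (-32.9 in wild-type and -21.0 in Neil3-null), the sarcoplasmic calcium pump gene Atp2a2 (-19.5 and -20.8), Popdc2 (-17.9 and -25.4), Cryab (-47.7 and -29.5), the cardiac transcription factor gene Gata6 (-25.9 and -28.7), Cavin1 (-19.0 and -30.6) and the mitochondrial malate dehydrogenase gene Mdh2 (-19.1 and -25.5). The genes higher in both included Il17ra (72.1 and 37.1), the immune checkpoint ligand gene Cd274 (35.5 and 27.8), the myeloid receptor gene Siglece (40.7 and 27.3), Dok3 (25.8 and 24.4), the lysosomal protease gene Ctsz (30.5 and 24.04) and Car2 (39.1 and 45.5). These examples were chosen after their values were seen. Across genes, which are not independent replicates, the infarct difference correlated between genotypes at r = 0.324 (Spearman 0.2998) for the unmodified index, 0.217 (0.165) for 5mC at gene ends and 0.134 (0.0958) for gene-body 5hmC. Of 499 genes past the threshold in wild-type, 373 (74.7%) had the same sign in Neil3-null.

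**Figure D3:**
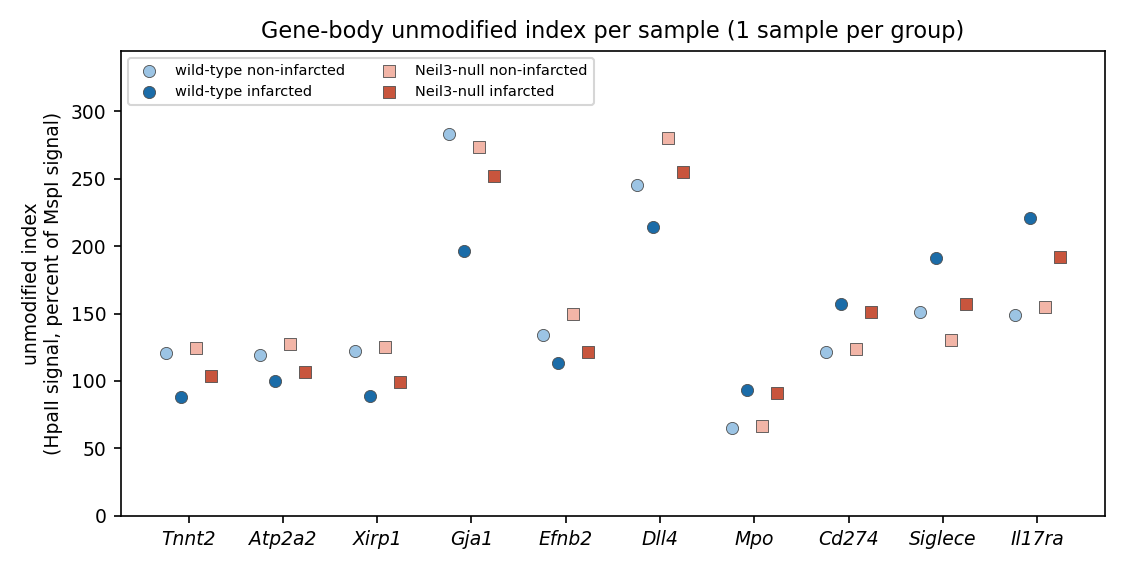
Gene-body unmodified index (y axis, HpaII signal as a percent of MspI signal) of 10 genes in each of the 4 samples, with 1 point per sample and no replicates; the genes were chosen after their values were seen. The first 6 genes were lower in infarcted than in non-infarcted tissue in both genotypes (Tnnt2 by -32.9 and -21.0), and the last 4 were higher (Il17ra by 72.1 and 37.1).

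The genotype comparison in non-infarcted ventricle sets Neil3-null against wild-type tissue, which also differed in the blocks of missing sites. The labels place this tissue, too, 3 days after infarction, and do not say whether it came from the same hearts as the infarcted tissue. Each sample used here also enters an infarct comparison above, so the values below are not separate observations. Most lists lay close to the median gene in the gene-body unmodified index. Cardiomyocyte markers were at 1.17 (percentile 82.8), leukocyte markers at -0.868 (percentile 29.0) and base excision repair at -2.31 (4 of 15 members above the median gene). Oxidative metabolism alone lay outside the central 95%, at -2.89 (percentile 1.95; 5 of 16 members above the median gene), with Esrra, a regulator of mitochondrial genes, at -8.98 ± 9.16, Ucp3 at -3.66 ± 11.8, Sdhb at 11.3 ± 8.02 and Hadha at 9.78 ± 7.43. At a minimum signal of 20 the list's percentile was 15.3. At gene ends, the proliferation list had a 5mC median of 23.0 relative to the median gene (percentile 99.8, 10 of 12 members above it), with Rrm2 at 77.6 ± 95.03, Rb1 at 40.6 ± 16.5, Ccnd1 at -50.7 ± 49.1 and Plk1 at -41.7 ± 24.1. It lay at 1.37 (percentile 96.2) when levels were clipped per site. In gene-body 5hmC, endothelial markers lay at 6.64 (percentile 98.5), with Dll4 at 53.7 ± 15.6, Tal1 at 33.8 ± 17.6, Ephb4 at -9.54 ± 5.04 and Vwf at -9.26 ± 3.29. The list's percentile was 98.0 at a minimum signal of 20. In this comparison 1 list lay outside the central 95% in each measure. Random draws of genes would give 0.75 of 15 lists in the unmodified index and in 5hmC, and 0.6 of 12 in 5mC.

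The gene-body unmodified index was higher in Neil3-null non-infarcted tissue at 152 and lower at 77 genes, or 69 and 130 relative to the median gene (51 and 149 at equal totals), against 227 in the simulation. Grpel2 (54.3 ± 22.1), Jph4, Dhh, Pus7l and Zfp446 had the most positive differences and Pax9 (-46.3 ± 23.8), Prxl2a, Fosb, Ankrd10 and Nr2e1 the most negative differences. The 5mC index at gene ends was higher at 476 and lower at 1404 genes (866 and 1012 relative to the median gene, against 1383 in all in the simulation; 426 and 164 after rescaling; 798 and 568 without the C+mC libraries). The calcium store gene Casq2 (91.9 ± 25.03 over 5 sites) was among the most positive differences, with Cep76 and Psmg2, which share 5 sites, Ubp1 and Mynn. Pdpn (-217 ± 97.2), Nfkbia (-173 ± 62.1), Nadk2 (-173 ± 221, and 87.9 without 1 of its 5 sites), Fbxl19 and Bmpr2 had the most negative differences. The gene-body 5hmC index was higher at 463 and lower at 203 genes (528 and 156 relative to the median gene, 684 in all against 231 in the simulation), and higher at 4 and lower at 145 after rescaling. Dact3 (87.0 ± 36.2), Pax9, Adcyap1, Prss56 and Gja1 (68.6 ± 25.6) had the most positive differences and Wdr6 (-41.2 ± 12.2), Chrna5, Bspry, Zbtb5 and Ttc37 the most negative differences. These differences again use the C+mC library that stood apart.

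In infarcted ventricle, Neil3-null tissue had a higher gene-body unmodified index than wild-type at cardiomyocyte markers (4.92 relative to the median gene, percentile 99.8, 17 of 23 members above it) and at endothelial markers (5.15, percentile 99.7, 16 of 20). Gja1 was at 55.9 ± 16.2, the mitochondrial creatine kinase gene Ckmt2 at 21.6 ± 8.93, Dll4 at 41.2 ± 21.0 and Egfl7 at 28.6 ± 9.93. Ckm (-15.1 ± 14.2), Tbx20 (-12.8 ± 11.3), Tal1 (-30.7 ± 40.9) and Erg (-7.89 ± 2.61) went the other way. Each sample used here also enters an infarct comparison above, so these values are not separate observations. In the wild-type infarct comparison, which shares the wild-type infarcted sample, the genes named so far in this paragraph all differed in the opposite direction. The proliferation list was lower, at -5.001 (percentile 1.18), led by the cell cycle inhibitor genes Cdkn1a (-37.7 ± 21.0) and Cdkn2a (-33.8 ± 34.1), with Trp53 at 13.8 ± 17.9 and E2f8 at 6.78 ± 6.09; at a minimum signal of 20 its percentile was 22.5. Leukocyte markers lay at -0.279 (percentile 43.9) and inflammation at -0.0522 (percentile 56.5). In this comparison 173 genes were higher and 121 lower, or 134 and 143 relative to the median gene (127 and 131 at equal totals), against 227 in the simulation. Adamts4, in the chromosome 1 block of missing sites, had the most positive difference (59.5 ± 33.1), followed by Gja1, Pvalb, Acad12 and Lsm11. The most negative differences were at Clcn3 (-65.1 ± 30.6), Hmx2, Pianp (-53.3 ± 55.5), Fbxo33 and Ppp2cb, the last in a chromosome 8 block.

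At gene ends, the 5mC index was higher in Neil3-null infarcted tissue at 1303 and lower at 459 genes (847 and 796 relative to the median gene, against 1383 in all in the simulation; 176 and 250 after rescaling; 1046 and 568 without the C+mC libraries). Atg9a and Ankzf1, which share 5 sites (176 ± 139), Gabra2, Gemin6 and Sh3bp1 (149 ± 164) had the most positive differences, and Pde9a (-150 ± 112), Hoxa2, Stmn4 (-107 ± 19.9), Ncoa1 and Lrp6 the most negative differences. The gene-body 5hmC index was higher at 65 and lower at 125 genes (109 and 109 at equal totals), and relative to the median gene 94 and 97, 191 in all, against 231 in the simulation; after rescaling 16 were higher and 2 lower. Zfp445 (35.9 ± 21.1), Spdye4b, Lrrc51, Fam135a and Ap1g1 (30.9 ± 7.08) had the most positive differences. Pvalb (-52.5 ± 25.4), Oasl1, Timd2, Vsig10l and Tshz3 (-34.1 ± 33.2, and -1.16 without 1 of its 70 sites) had the most negative differences. None of the lists stood apart in 5mC or 5hmC.

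The genotype difference was nearly uncorrelated across genes between the tissues: r was 0.0685 (Spearman 0.0457) for the unmodified index, -0.0197 for 5mC at gene ends and -0.00627 for gene-body 5hmC. In the unmodified index, 13 genes were higher and 27 lower in both tissues, against 0.949 and 1.91 if independent, and 15 went opposite ways. No expected number was computed for the opposite ways. Genes that vary widely could pass in both tissues in any direction, so the excess over independence is not by itself agreement. In the additive model over the 4 samples, limma called 0 genes at an adjusted p under 0.05 for infarct or genotype in any of the 3 measures. The smallest adjusted p for infarct was 0.210 for the unmodified index, 0.182 for 5mC and 0.781 for 5hmC. At an unadjusted p under 0.05, 988 gene bodies had a higher and 319 a lower unmodified index in infarcted tissue, against 487 expected by chance in both directions together, and 586 and 141 for genotype. At equal totals these numbered 560 and 557 for infarct and 301 and 290 for genotype. After rescaling on unmethylated gene ends they numbered 807 and 420 for infarct and 1501 and 71 for genotype. The lean towards higher values thus depends on the scaling. For 5mC at gene ends, 418 genes passed for infarct (3 higher and 415 lower) and 136 for genotype, against 206 expected. For 5hmC 600 (360 higher and 240 lower) and 472 passed, against 487. After that rescaling on unmethylated gene ends, the infarct effect had 269 higher and 110 lower genes in 5mC, and 5 higher and 1985 lower in 5hmC. There limma used the same variance for every gene, so these counts follow the size of the difference alone.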

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

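All tests of explanations in this part were chosen after the results were seen. Sites missing from both Neil3-null samples formed 3 blocks, with 21.7% and 9.84% of wild-type sites missing on chromosome 8 and 16.0% on chromosome 1, in sites that no comparison above uses. A lower depth of the null libraries would act alike at sites of like signal, but at sites with at least the median wild-type signal the share missing was at least 6.81% in each block (46 of 676 sites in the lowest), against 0.242% on the other autosomes. A deletion would remove nearly all sites, but at least 78.3% of the wild-type sites of each block were still listed. DNA kept beside the targeted gene cannot give the chromosome 1 block, since Neil3 lies on chromosome 8. The choice of bins by their missing sites did not make the chromosome 1 block: in bins there chosen by every other site, 15.9% of the remaining sites were missing, against 0.575% outside such bins. This split says nothing about its cause. For the chromosome 8 blocks DNA of another mouse strain stays open, as does such DNA elsewhere in the genome, since the breeding history is not given and no test apart from the missing sites was run.

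The 5mC index at gene ends was lower in infarcted than in non-infarcted wild-type tissue, with a median gene at -23.5 percentage points. The makeup of the C+mC library of wild-type non-infarcted tissue is a possible explanation: its correlation with the MspI library of the same sample was 0.551, against 0.709 in the lowest other sample. The scaling of the libraries is another, and it stays open. The median gene moved to 8.98 once the libraries were rescaled on unmethylated gene ends. That rescaling is set on gene ends themselves and moves their 5mC index by construction, so the turn in sign cannot decide this. With the libraries rescaled to equal totals, the median gene was still lower in infarcted tissue, at -16. Whether the infarct response differs between the genotypes stays open: the Neil3-null median was -5.06, but with 1 sample per group there is no spread between animals. The wild-type and Neil3-null medians were 8.98 and 2.33 after rescaling on unmethylated gene ends, and -16 and -2.78 at equal totals.

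In infarcted tissue of both genotypes, the gene-body unmodified index was lower at cardiomyocyte markers and higher at leukocyte markers, the latter at 3.30 (percentile 90.3) in wild-type at a minimum signal of 20. Equal totals moved the median gene in wild-type from 2.99 to -0.202. The cardiomyocyte medians were then at most -8.17, below all random lists, and the leukocyte medians at least 4.56 (percentile 99.03). This does not test scaling by 1 factor per library, which moves a list and random lists of like index together and could hardly change their order. In wild-type the markers of other cell types did not move alike: the endothelial median was -7.33 (percentile 0.01) and the leukocyte median 5.31 (percentile 98.6). Loss of cardiomyocytes alone would move them alike only if each list is less modified in its own cell type. That was not tested, so these medians cannot decide it. In Neil3-null the endothelial median was -2.43 (percentile 2.06, and 13.1 at a minimum signal of 20). Loss of cardiomyocytes alone, the normalization of the libraries, a change in several cell types and a change of modification within cells stay open. There was no test apart from the marker medians themselves.

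Gene lists whose median lay on opposite sides of the median gene in the groups compared, and outside the central 95% of random lists in at least 1 of them, are given as values; the differences themselves were not tested. Base excision repair differed in its infarct difference by -8.78 percentage points of the gene-body unmodified index between wild-type (-6.48) and Neil3-null (2.30). Between non-infarcted and infarcted tissue, the genotype difference in this index differed by -5.68 at endothelial markers, -6.42 at oxidative metabolism and 6.68 at proliferation genes. In the 5mC index at gene ends, the genotype difference of the proliferation list differed by 25.4 between the tissues. In gene-body 5hmC, endothelial markers differed by 7.19 between genotypes in the infarct difference and by 8.11 between tissues in the genotype difference. Both use the C+mC library that stood apart. For each gene both are the same contrast of the same samples and only the medians differ, so they are not separate observations.

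On chromosome Y between 6 and 58 Mb, outside the autosomes used above, 562 sites were listed in Neil3-null non-infarcted and 554 in Neil3-null infarcted tissue, against 127 and 120 in the wild-type samples, of 599 listed in any sample. The median MspI signal there was 10.7 and 11.0 in Neil3-null and 2.19 and 2.74 in wild-type tissue. The rest of chromosome Y was listed alike in all samples. Below 6 Mb, 593 and 575 sites were listed in wild-type and 578 and 589 in Neil3-null tissue, non-infarcted first. From 58 Mb on, these numbered 259 and 243 in wild-type and 249 and 250 in Neil3-null tissue.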

How the results depend on the processing

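The signs of the cardiomyocyte medians in infarcted tissue held under every setting, below all random lists (-13.7 to -2.88), though 1 factor per library moves all genes one way. A count was taken as kept within 1.5 times its value, a genome-wide value within its SD over autosomes, and a correlation within its standard error over autosomes. A list was kept by its side of the central 95%, whatever its size, and by its sign only if it lay outside at first. Most lists lay inside at first, and those that stayed inside counted as kept. By these rules 678 of 708 list values were kept, while 12 lost their place outside, 17 gained a place there and 1 turned sign. Of 194 main values 121 were kept, among them the genome-wide 5hmC infarct difference in wild-type, -0.207 at a minimum signal of 20 against 0.584. The values below were not; the cause was not tested, except that a higher site minimum or a wider window changes the number of genes measured, and rescaling on unmethylated gene ends shrinks the unmodified index by construction. No paired analysis was possible because the labels give no animal numbers and each group has 1 sample. With unknown depth, noise at sites of low signal cannot be set apart from differences. The planned promoter window was not run, for want of strand. Values are listed in the order infarct in wild-type, infarct in Neil3-null, genotype in non-infarcted, genotype in infarcted tissue.

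Genes past the threshold in the gene-body unmodified index numbered 343, 150, 119 and 171 at a minimum signal of 20, and 6, 0, 0 and 2 after rescaling on unmethylated gene ends. For 5mC at gene ends they numbered 1015, 285, 590 and 426 after that rescaling, 5818, 3250, 4457 and 3660 with a 2 kb window (chosen after seeing the data), and 7293, 4925, 5999 and 5532 with at least 3 sites. In the last 3 comparisons they numbered 2575, 2905 and 2835 at a threshold of 10 and 787, 1185 and 1058 at 30 percentage points. For gene-body 5hmC they numbered 1643, 24, 149 and 18 after rescaling, 237, 22, 159 and 31 with at least 20 sites, 3147, 1553, 2827 and 1666 at a threshold of 10, and 273, 16, 190 and 20 at 30.

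The correlation of the infarct difference between genotypes was 0.307 for the unmodified index at equal totals, and 0.159 for 5mC and 0.111 for 5hmC after rescaling on unmethylated gene ends. That of the genotype difference between tissues was 0.0873, 0.0438 and 0.0858 for the unmodified index at a minimum signal of 5, of 20 and at equal totals. It was 0.00146 for 5mC at a minimum of 20, and 0.0262 for 5mC and 0.0396 for 5hmC after rescaling.

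The genome-wide 5mC difference turned to 14.3, 3.61, 7.18 and -3.51 after rescaling; as a median of clipped levels it turned to 0.719, 0.434 and 1.21 and was 0.929. At a minimum signal of 20 it was -2.80 and -0.223 for infarct. The 5hmC difference was -15.1, -3.86 and -9.16 after rescaling and turned to 2.03 in the last comparison, where the clipped median was 0.

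The leukocyte median in wild-type infarct was 5.03 (percentile 97.46) at a minimum signal of 5 and 3.30 at 20. Lists outside the central 95% numbered 8 instead of 13 for the unmodified index at a minimum of 20, 5 instead of 2 for 5mC after rescaling, and 1 instead of 2 for 5hmC at a minimum of 20. The oxidative metabolism 5mC median in Neil3-null infarct was 0 when clipped. After rescaling, limma called 31 genes for infarct in 5mC, 9 for genotype in 5mC and 5 for infarct in 5hmC, and at a minimum signal of 5 it called 1 gene for infarct in the unmodified index, each against 0. In 5mC and 5hmC after rescaling, limma used the same variance for every gene. Those calls therefore pick genes by the size of the difference alone.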

Other observations

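Further genes had a higher gene-body unmodified index in infarcted tissue of both genotypes. Pax6 differed by 30.5 in wild-type and 27.8 in Neil3-null, Nr2e1 by 25.1 and 35.0, Lmo4 by 32.1 and 33.5, Snx5 by 35.2 and 33.6 and Trib1 by 55.4 and 21.4 percentage points. The genes lower in both included the methyl-CpG binding gene Mbd2 (-21.3 and -20.9), the uracil glycosylase gene Smug1 (-33.7 and -24.2), the RNA-binding gene Qk (-21.6 and -21.4), Map7d1 (-26.0 and -23.5) and Lbh (-21.7 and -24.7). These genes were named after their values were seen.

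Gene-body differences repeated only in part within a gene. When the sites were split by their order into odd and even sites, the difference of the unmodified index correlated between the 2 sets at r = 0.176 for infarct in wild-type, 0.121 for infarct in Neil3-null, 0.0401 for genotype in non-infarcted tissue and 0.0235 for genotype in infarcted tissue, across 9739 genes. In the same order r was 0.328, 0.128, 0.213 and 0.0507 for gene-body 5mC and 0.278, 0.0693, 0.266 and 0.0238 for 5hmC, where the infarct comparison in wild-type and the genotype comparison in non-infarcted tissue use the C+mC library that stood apart.

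Chromosome X sites had a median MspI signal of 9.96 to 11.7 in the 4 samples, against 26.0 to 31.7 on the autosomes.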
